A study of Mus musculus with 18 samples.

How the data were processed

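Total RNA from mouse sciatic nerve was profiled on Illumina whole-genome expression arrays, 1 array per sample. The labels give animals of 2 months (young here) and 24 months (old here), taken on day 0 or on day 1 or 4 after crush of the nerve. That makes 6 groups of 3 arrays and 18 arrays in all. The day 0 samples are labelled con and the others inj, read here as uninjured control and injured nerve. The labels do not say whether the 3 arrays of a group come from separate animals, so every p-value here measures the spread between these samples only.

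The authors deposited a table of non-normalized values and a table of processed values. In the first, the deposited unit is the linear bead intensity of each of 25697 probes, neither background-subtracted nor normalized between arrays, without detection p-values and without control probes. In the second, the deposited intensity values are on a linear scale and quantile-normalized between the 18 arrays: sorted values of the columns differed by at most 0.0385%, and each array ranked its probes as in the first table (lowest rank correlation 1). Per the submitters' processing notes RMA was used, with no version and no step named. The platform's scanner software is not stated.

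The non-normalized intensities were corrected with the normexp method of limma 3.58.1 in R 4.3.3 (offset 50, no control probes), quantile-normalized and put on the log2 scale. Log2 values and fold changes below are on this scale, which keeps differences among dim probes small. Because the table has no detection p-values, a choice made once it had been read was to take background from the lower side of each array's intensity peak, and a probe counted as above background at p under 0.05 of that distribution. Between 53.5% and 62.5% of the probes on an array were above background. Probes above background on at least 3 arrays were kept (17234 of 25697). Probe names were brought to the GRCm38.p6 annotation through the Entrez ID (16938 probes), the RefSeq accession (7420) or the symbol (465), and 874 kept the symbol of the table. Of several probes for a gene the brightest was used, which left 12529 genes tested. The probe coordinates in the table name no genome build, so no positions are given. Raw median intensities ran from 110.7 to 135.3 and raw upper quartiles from 200 to 339. The number of arrays limits the precision.

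One linear model with a mean for each of the 6 groups was fitted to all 18 arrays with lmFit and eBayes of limma, and each comparison was a contrast of these means. Adjusted p-values are Benjamini-Hochberg values over the 12529 genes of that comparison, and a gene was called at an adjusted p under 0.05. An exact permutation test of 3 arrays against 3 cannot go below 0.10 two-sided. Errors beside log2 fold changes are standard errors from the model with n = 3 arrays per group, and errors beside levels are SDs over 3 arrays. Where the arrays of the lower group lay near background, at most a lower bound of the fold was given.

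Before the data were examined, the model, the comparisons, 38 gene lists and the rule for named genes were fixed. For each of the 9 main comparisons (4 of injury, 3 of age, 2 interactions) the rule names the 5 genes with the largest rise and the 5 with the largest fall among called genes with a standard symbol and, in the injury and age comparisons, with all 3 arrays of one group above all 3 of the other. It adds up to 4 members of each list described, those with the smallest adjusted p, and a fixed set of genes of Schwann cell repair and myelination, among them Jun, Shh, Olig1, Gdnf, Ngfr, Sox2, Mbp and Egr2. Of the genes that the rule names, 3 are not reported here. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists, then with an estimated correlation and with fry. Counts of list members are over all genes tested unless given as adjusted over the list alone.

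The pipeline was tested on simulated data with 50 genes at each of 4 true changes. At a log2 change of 1 it found 98% in a comparison of young day 4 with young day 0, 94% in old against young at day 4 and 76% in the interaction at day 4, and at 0.5 it found 32%, 46% and 8%. The false calls numbered 7, 10 and 8, with 0 sign errors. The simulated noise was normal and independent between genes and arrays, so these figures need not hold for the real arrays.

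Alternatives fixed in advance were no background correction, cyclic loess, the authors' processed values, no filter and a stricter filter on dim probes, the mean of a gene's probes, a floor of 2-fold, only the compared groups, the replicate number as a block, array weights, an intensity trend, and leaving out each array in turn. Chosen after seeing the data were the array's upper quartile as a covariate for brightness, blocks of 8 by the running number in the sample descriptions (an array slide of this kind holds 8 samples, and the files name none), and leaving out the 5 arrays, or the 4 arrays, whose skeletal muscle list lay more than 1 or 1.5 log2 units above the median array. With these blocks only young day 1 against day 0 and the ages at day 0 do not rest on 1 array; the others rest on young day 1 replicate 3, on old day 4 replicate 1 or on both. A slide term was left out because no slide is named, and a background correction by detection p-values or control probes because the table holds neither.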

Results

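Gene expression was measured in 18 samples of mouse sciatic nerve, 3 for each of 2 ages (2 and 24 months) and 3 times (day 0 as control, day 1 and day 4 after crush). Correlations between 2 arrays of one group lay between 0.974 and 0.993, and the first 3 principal components held 50.7%, 19.5% and 7.08% of the variance. The raw upper quartiles of the 3 old day 0 arrays (lowest 256) lay above those of the 3 young day 0 arrays (highest 229). Skeletal muscle markers lay more than 1 log2 unit above the median array on 5 arrays: old day 0 replicate 2 (4.14 above), old day 1 replicate 2 (2.73), young day 1 replicate 2 (2.46), young day 0 replicate 3 (1.76) and old day 0 replicate 1 (1.04). No day 4 array was among them.

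The first question was how the nerve of young animals had changed 1 day after crush. Shh, the ligand of the hedgehog pathway that Schwann cells make after injury, rose 37.4-fold (log2 fold change 5.22 ± 0.21), and Gdnf, a survival factor for motor neurons, rose 24.8-fold (4.63 ± 0.14). Also among the largest rises were those of Arg1, an arginase of alternatively activated macrophages (5.56 ± 0.38), the platelet chemokine Ppbp (4.90 ± 0.55), the metalloprotease inhibitor Timp1 (4.83 ± 0.18) and the neutrophil gene S100a8 (4.71 ± 0.67). Among the largest falls were those of Inmt (-2.51 ± 0.36), Nrn1 (-1.90 ± 0.27), Ces1d (-1.80 ± 0.47) and Angptl7 (-1.53 ± 0.38). The largest limma adjusted p among these genes was 0.00929.

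Inflammatory genes led the rise at day 1 in young nerve. Of 30 measured cytokines and chemokines 20 rose and 0 fell (adjusted over the list alone 22 rose; median log2 fold change 1.67, camera adjusted p = 4.9e-14). Examples were Ccl7 (3.51 ± 0.23), Cxcl14 (2.60 ± 0.21) and the acute-phase gene Saa3 (3.59 ± 0.31). Of 23 macrophage markers 17 rose and 6 were not called (18 adjusted over the list alone; median log2 fold change 1.15, camera adjusted p = 4.6e-12). Examples were Lgals3 at 1.82 ± 0.12, Cd68 at 2.50 ± 0.30 and the lipid receptor Trem2 at 1.60 ± 0.22. Of 19 neutrophil markers 12 rose, as adjusted over the list alone (median log2 fold change 1.21, camera adjusted p = 7.4e-07, and adjusted p = 0.135 with an estimated correlation). S100a9 changed by 4.05 ± 0.59. Of 14 genes of alternatively activated macrophages 8 rose (adjusted over the list alone 8 rose and 1 fell; median log2 fold change 0.84, camera adjusted p = 1.5e-05). Examples were Socs3, a feedback inhibitor of cytokine signalling (2.77 ± 0.18), and Pf4 (2.18 ± 0.22).

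Of 20 immediate early genes 10 rose and 1 fell (12 and 1 adjusted over the list alone; median log2 fold change 0.62, camera adjusted p = 4.3e-07). Examples were Fos at 2.29 ± 0.23, Junb at 2.30 ± 0.23 and Egr1 at 2.16 ± 0.25. Of 19 neurotrophic factors 8 rose and 1 fell (10 and 1 adjusted over the list alone; median log2 fold change 0.35, camera adjusted p = 1.2e-04). An example was the ciliary neurotrophic factor relative Clcf1 (2.19 ± 0.18). Of 32 cell cycle genes 16 rose and 1 fell (20 and 1 adjusted over the list alone; median log2 fold change 0.36, camera adjusted p = 2.6e-09). The 4 named ones, Uhrf1 (2.05 ± 0.17), Mcm5 (2.03 ± 0.21), Mcm2 (1.38 ± 0.16) and Chaf1b (1.12 ± 0.11), act in DNA replication and chromatin assembly. Myelin genes had begun to fall: of 21, 13 fell and 1 rose (14 and 1 adjusted over the list alone; median log2 fold change -0.61, camera adjusted p = 1.1e-04, and adjusted p = 0.113 with an estimated correlation). Examples were Ugt8a, which makes the myelin lipid galactosylceramide (-1.28 ± 0.17). Of 13 fatty acid synthesis genes 6 fell and 0 rose (9 adjusted over the list alone; median log2 fold change -0.35, camera adjusted p = 0.00258). Elovl6 changed by -1.02 ± 0.14. Ngfr, the low-affinity neurotrophin receptor of repair Schwann cells, rose by 0.71 ± 0.16. Jun (0.29 ± 0.17, adjusted p = 0.240), Sox2 (0.09 ± 0.14, adjusted p = 0.699) and Egr2 (0.22 ± 0.17, adjusted p = 0.390) did not pass and Olig1, at background in young day 1 nerve, fell at least 1.20-fold. The brightest probe of Mbp lay near the top of the intensity scale on days 0 and 1 (SD 0 in young day 0 nerve after normalization), where a difference can be understated or hidden, so values of Mbp are given for the ages at day 4 alone. There, as in most comparisons, 1 of its 2 other probes had the opposite sign.

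In this comparison 3266 of 12529 genes passed, 1377 higher and 1889 lower on day 1, and 423 of them differed at least 2-fold. Of the 38 lists 21 were called, and 10 of these held with an estimated correlation. Without the 4 arrays richest in muscle RNA, a choice made after seeing the data, 1731 genes passed, within the 1401 to 2758 that leaving out 1 array from each of the same 4 groups gave in all 81 ways. The calls of Ces1d and Olig1 ended in at least 1 alternative.

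By day 4 young nerve had lost most of its myelin gene expression and had taken on genes of dividing cells. Prx, a scaffold protein of myelinating Schwann cells, fell 44.2-fold, from a log2 intensity of 12.39 ± 0.04 to 6.93 ± 0.21 (SD, n = 3 each; log2 fold change -5.47 ± 0.14). Also among the largest falls were those of Fa2h, which makes the hydroxylated fatty acids of myelin (-6.16 ± 0.19), Ncmap (-6.01 ± 0.21) and the spectrin Sptb (-4.80 ± 0.13). The largest rises were those of Shh (45.7-fold, 5.51 ± 0.21), Gdnf (42.9-fold, 5.42 ± 0.14), the mitotic genes Prc1 (5.24 ± 0.16) and Pbk (5.07 ± 0.16), and Arg1 (4.69 ± 0.38). Every gene in these sentences had an adjusted p of 4.2e-08 or less with limma.

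Of 21 myelin genes 18 fell and 0 rose, the same counts as adjusted over the list alone (median log2 fold change -2.35, camera adjusted p = 1.1e-19). Examples were Cldn19 (-4.27 ± 0.11), Mag (-3.77 ± 0.11) and Egr2, the transcription factor that drives myelination (-2.35 ± 0.17). Of 19 cholesterol synthesis genes 16 fell, also adjusted over the list alone (median log2 fold change -1.36, camera adjusted p = 2.8e-10). Examples were Hsd17b7 at -2.80 ± 0.16, Hmgcs1 at -2.63 ± 0.16 and Cyp51 at -2.51 ± 0.16. Of 13 fatty acid synthesis genes 9 fell (9 adjusted over the list alone; median log2 fold change -1.17, camera adjusted p = 1.9e-05). Elovl6 changed by -2.71 ± 0.14.

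Of 32 cell cycle genes 29 rose and 1 fell, also adjusted over the list alone (median log2 fold change 2.50, camera adjusted p = 2.4e-28). Examples were Birc5 at 4.16 ± 0.11, Top2a at 4.21 ± 0.13 and Kif22 at 3.22 ± 0.09. Of 18 genes of repair Schwann cells 11 rose and 1 fell, also adjusted over the list alone (median log2 fold change 0.82, camera adjusted p = 3.5e-05). Examples were the growth factor Btc (4.08 ± 0.17), Ngfr (3.96 ± 0.16), Sox2 (1.75 ± 0.14) and Jun, the regulator of the repair state (1.65 ± 0.17). Olig1 rose by 0.39 ± 0.13 (adjusted p = 0.0276). Of 23 macrophage markers 20 rose (21 adjusted over the list alone; median log2 fold change 1.43, camera adjusted p = 9.4e-11, and adjusted p = 0.0720 with an estimated correlation). Trem2 changed by 3.52 ± 0.22 and Lgals3 by 2.78 ± 0.12. Of 21 genes for lipid uptake and lysosomes of phagocytes 11 rose and 2 fell (14 and 2 adjusted over the list alone; median log2 fold change 0.47, camera adjusted p = 1.3e-04). Examples were the acid hydrolase Hexa at 1.59 ± 0.15, Soat1, which stores cholesterol as esters, at 1.62 ± 0.16 and Gas6, a bridge between phagocytes and dying cells, at -1.60 ± 0.12. Adipocyte markers were lower as well: 13 of 17 fell (14 adjusted over the list alone; median log2 fold change -1.20, camera adjusted p = 2.9e-05, and adjusted p = 0.278 with an estimated correlation), the hormone gene Lep by -3.46 ± 0.50. With running-number blocks the adjusted p of that list was 0.0574.

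Between day 0 and day 4 in young nerve 4688 genes passed, 2300 higher and 2388 lower, and 1254 differed at least 2-fold. Of the 38 lists 17 were called and 6 held with an estimated correlation. With blocks by running number, chosen after seeing the data, 2212 genes passed. In this and all later comparisons but that of the ages at day 0, these blocks make the result rest on 1 array of young day 1, of old day 4 or of each, so a call lost with them is no evidence of no change. The calls of Olig1 and Lep ended in at least 1 alternative.

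**Figure D1:**
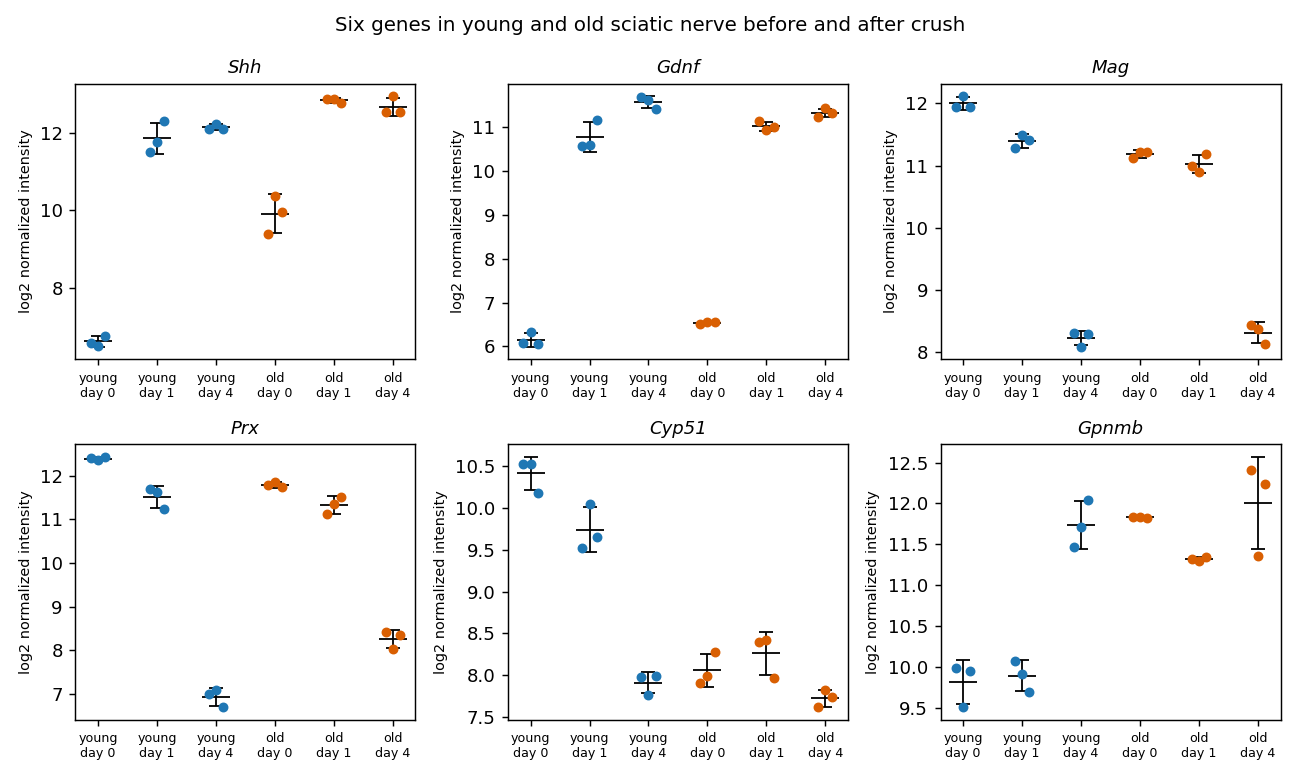
Log2 normalized intensity of 6 genes in the 6 groups (points, 3 arrays per group; bar, mean; whisker, SD). Shh stood at 9.91 ± 0.50 in old day 0 nerve and at 6.63 ± 0.13 in young day 0 nerve.

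In old animals the same comparison of day 1 with day 0 asked how the aged nerve responds early. Arg1 rose 58.9-fold (log2 fold change 5.88 ± 0.38), followed by the neutrophil genes S100a8 (5.66 ± 0.67) and S100a9 (5.63 ± 0.59), the inflammatory cytokine Il1b (4.99 ± 0.78) and Gdnf (4.49 ± 0.14). Shh rose 7.58-fold (2.92 ± 0.21). The largest falls were those of Inmt (-3.30 ± 0.36), the smooth muscle myosin Myh11 (-3.05 ± 0.60), Cyp2e1 (-3.02 ± 0.52), Cytl1 (-3.01 ± 0.50) and Nnat (-2.68 ± 0.50), all with a limma adjusted p of 0.00142 or less.

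Of 30 cytokines and chemokines 19 rose (21 adjusted over the list alone; median log2 fold change 1.25, camera adjusted p = 3.6e-12). Examples were Ccl7 at 3.08 ± 0.23 and Saa3 at 3.54 ± 0.31. Of 19 neutrophil markers 11 rose (13 adjusted over the list alone; median log2 fold change 1.54, camera adjusted p = 2.4e-09, and adjusted p = 0.109 with an estimated correlation), and of 23 macrophage markers 11 rose, also adjusted over the list alone (median log2 fold change 0.56, camera adjusted p = 1.6e-05, and adjusted p = 0.165 with an estimated correlation). Lgals3 changed by 1.31 ± 0.12 and Fcgr1 by 1.23 ± 0.20. Of 20 immediate early genes 11 rose and 1 fell, also adjusted over the list alone (median log2 fold change 0.66, camera adjusted p = 1.9e-08). Examples were Fos at 2.27 ± 0.23 and Junb at 2.27 ± 0.23. Of 19 neurotrophic factors 8 rose (9 adjusted over the list alone; median log2 fold change 0.42, camera adjusted p = 5.0e-05). Examples were Clcf1 (2.16 ± 0.18) and Il11 (1.18 ± 0.12). Of 18 unfolded protein response genes 7 rose and 1 fell (9 and 2 adjusted over the list alone; median log2 fold change 0.33, camera adjusted p = 0.00135). Examples were the chaperone Calr at 1.06 ± 0.20 and the transcription factor Xbp1 at 0.73 ± 0.09. Of 23 matrix proteases and inhibitors 11 rose and 3 fell (12 and 3 adjusted over the list alone; median log2 fold change 0.42, camera adjusted p = 0.00142). Timp1 changed by 4.28 ± 0.18 and Adamts4 by 1.93 ± 0.18. Of 17 adipocyte markers 13 fell (14 adjusted over the list alone; median log2 fold change -1.12, camera adjusted p = 7.5e-08, and adjusted p = 0.131 with an estimated correlation). Aqp7 changed by -1.65 ± 0.19. Jun rose by 0.78 ± 0.17 and Egr2 by 0.84 ± 0.17, and Ngfr (0.43 ± 0.16), Sox2 (0.12 ± 0.14) and Olig1 (-0.15 ± 0.13) did not pass.

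In old nerve 2883 genes passed at day 1, 1297 higher and 1586 lower, 488 of them at least 2-fold. Of 38 lists 23 were called, 5 of them also with an estimated correlation. With running-number blocks 442 genes passed, and without the 4 arrays richest in muscle RNA 1589, both chosen after seeing the data. The calls of Il1b, Myh11, Cyp2e1, Cytl1, Nnat, Fcgr1, Calr, Aqp7, Jun and Egr2 ended in at least 1 alternative.

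At day 4 old nerve also showed high repair and cell cycle genes and low myelin genes against its own day 0. Arg1 rose 40.4-fold (5.34 ± 0.38), Gdnf 27.7-fold (4.79 ± 0.14), Prc1 25.0-fold (4.64 ± 0.16), the vesicle gene Syt4 22.8-fold (4.51 ± 0.18) and Timp1 19.9-fold (4.32 ± 0.18). Among the largest falls were those of Ncmap (-5.28 ± 0.21), Fa2h (-4.82 ± 0.19), Sptb (-3.86 ± 0.13) and Smco3 (-3.74 ± 0.20). Egr2 fell by 1.38 ± 0.17. The largest limma adjusted p of these genes was 7.6e-06.

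Of 21 myelin genes 16 fell and 2 rose, also adjusted over the list alone (median log2 fold change -2.09, camera adjusted p = 7.3e-13). Cldn19 changed by -2.94 ± 0.11 and Prx by -3.53 ± 0.14. Of 32 cell cycle genes 28 rose and 1 fell, also adjusted over the list alone (median log2 fold change 1.99, camera adjusted p = 1.8e-26). Examples were Birc5 at 3.52 ± 0.11 and Top2a at 3.41 ± 0.13. Of 18 repair Schwann cell genes 9 rose, also adjusted over the list alone (median log2 fold change 0.60, camera adjusted p = 2.8e-05). Examples were Ngfr (3.04 ± 0.16), Shh (2.76 ± 0.21), Btc (2.54 ± 0.17), Sox2 (1.65 ± 0.14) and Jun (1.81 ± 0.17). Olig1 (0.27 ± 0.13, adjusted p = 0.131) did not pass. Of 23 macrophage markers 20 rose, also adjusted over the list alone (median log2 fold change 1.20, camera adjusted p = 5.5e-09, and adjusted p = 0.131 with an estimated correlation). Trem2 changed by 1.87 ± 0.22. Of 21 genes for lipid uptake and lysosomes of phagocytes 13 rose and 3 fell (14 and 3 adjusted over the list alone; median log2 fold change 0.51, camera adjusted p = 0.00651, and adjusted p = 0.0563 with an estimated correlation). An example was the fatty acid carrier Fabp5 at 1.29 ± 0.13. Of 28 genes for fibrillar collagens and matrix 14 rose and 6 fell, also adjusted over the list alone (median log2 fold change 0.52, camera adjusted p = 0.0122, and adjusted p = 0.363 with an estimated correlation), the matrix protein gene Tnc by 3.54 ± 0.29 and the microfibril gene Mfap5 by -1.64 ± 0.12. Without the 5 arrays richest in muscle RNA the adjusted p was 0.0594. Cholesterol synthesis was not among the called lists in old nerve (4 of 19 fell, 1 rose, median -0.01, adjusted p = 0.295).

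In old nerve 4426 genes passed at day 4, 2197 higher and 2229 lower, 1120 of them at least 2-fold. Of the 38 lists 17 were called, 3 of them also with an estimated correlation. With running-number blocks 1517 genes passed. The call of Egr2 ended in at least 1 alternative.

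Across all 12529 genes the fold changes of young and old nerve, from separate arrays, correlated at r = 0.848 at day 1 (Spearman 0.749) and r = 0.892 at day 4 (Spearman 0.794); genes are not independent replicates, so no p is given. At day 4, 1657 genes were higher at both ages (403 if the calls were independent), 1654 were lower at both ages (425 if independent) and 10 went opposite ways. At day 1 these counts were 931 (143 if independent), 1099 (239 if independent) and 1.

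**Figure D2:**
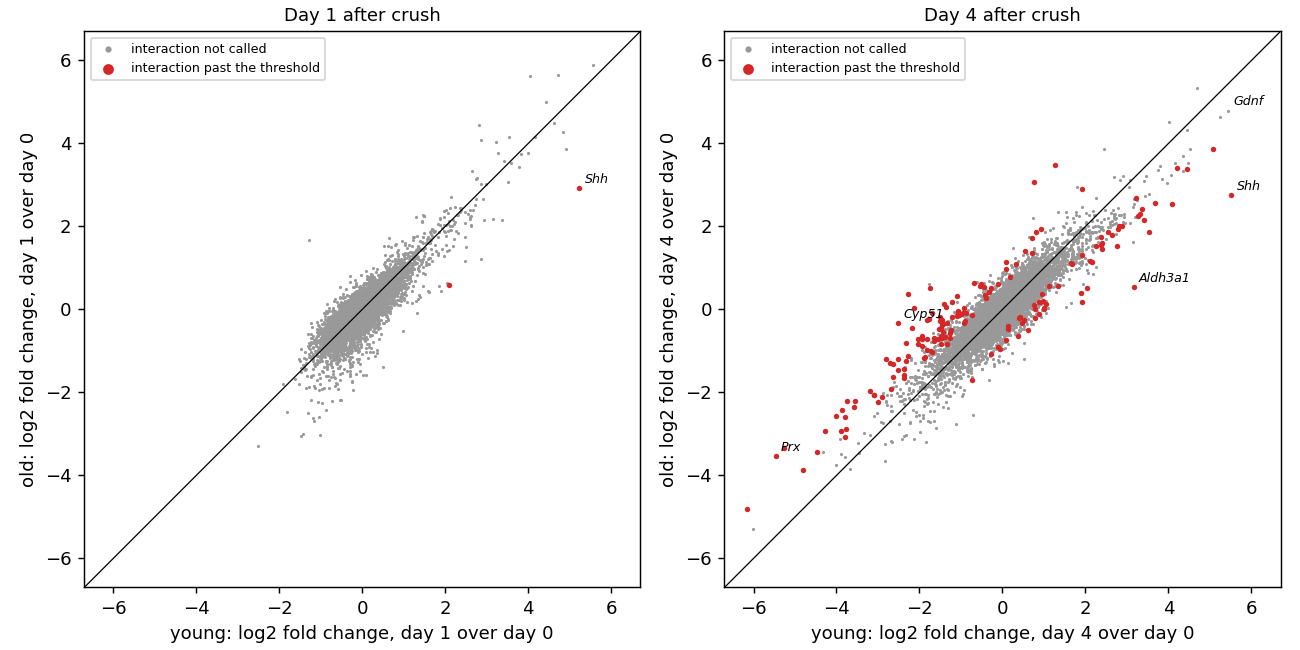
Log2 fold change over day 0 in old nerve against young nerve, 1 point per gene, at day 1 and day 4; red points passed the interaction test and the line marks equal change. At day 1, 2 genes were red and at day 4, 168.

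The next question was how uninjured old nerve differs from uninjured young nerve. Shh was 9.74-fold higher in old nerve at day 0 (9.91 ± 0.50 against 6.63 ± 0.13 log2 intensity, SD, n = 3 each; log2 difference 3.28 ± 0.21, limma adjusted p = 2.4e-07), while Gdnf (0.38 ± 0.14, adjusted p = 0.127, its other probe of opposite sign) was not called. Cholesterol synthesis genes were lower in old nerve: 17 of 19 passed (18 adjusted over the list alone; median log2 difference -1.22, camera adjusted p = 5.6e-29). Examples were Sqle (-2.40 ± 0.20), Cyp51 (-2.36 ± 0.16), Fdps (-2.14 ± 0.19) and Hsd17b7 (-1.67 ± 0.16). The mean level of this list in old day 0 nerve (7.87 ± 0.09) lay near that of injured nerve at day 4 (young 7.72 ± 0.03, old 7.68 ± 0.03) and below that of young day 0 nerve (9.09 ± 0.10). Gpnmb (2.01 ± 0.21), Trem2 (1.81 ± 0.22) and the lipid carrier Apoe (1.497 ± 0.22) were higher in old nerve.

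Of 13 fatty acid synthesis genes 6 were lower and 0 higher in old nerve (7 lower adjusted over the list alone; median log2 difference -0.45, camera adjusted p = 3.5e-08). Examples were Elovl6 at -1.73 ± 0.14 and Fads2 at -0.86 ± 0.12. Of 21 myelin genes 8 were lower (12 adjusted over the list alone; median log2 difference -0.49, camera adjusted p = 1.6e-10). Examples were Ugt8a at -1.66 ± 0.17 and Mag at -0.81 ± 0.11. Egr2 (-0.39 ± 0.17) did not pass, nor did Jun (-0.33 ± 0.17), Ngfr (0.40 ± 0.16), Sox2 (0.08 ± 0.14) and Olig1 (-0.09 ± 0.13). Of 28 genes for fibrillar collagens and matrix 9 were lower and 0 higher (14 lower and 2 higher adjusted over the list alone; median log2 difference -0.44, camera adjusted p = 8.2e-09, and adjusted p = 0.0650 with an estimated correlation). Examples were Col1a2 (-1.56 ± 0.22), Col6a2 (-1.29 ± 0.16) and Mfap5 (-1.18 ± 0.12). Of 23 macrophage markers 6 were higher (8 adjusted over the list alone; median log2 difference 0.54, camera adjusted p = 3.5e-08, and adjusted p = 0.120 with an estimated correlation). Ms4a7 differed by 1.37 ± 0.25. Of 21 genes for lipid uptake and lysosomes of phagocytes 6 were higher and 1 lower, also adjusted over the list alone (median log2 difference 0.05, camera adjusted p = 0.0154, and adjusted p = 0.0883 with an estimated correlation). The sign of the list's median turned with cyclic loess normalization (-0.03), and the call ended without young day 0 replicate 2 (adjusted p = 0.0505). The chemokine Ccl8 (2.32 ± 0.39), the retinol carrier Rbp7 (2.05 ± 0.34) and the complement genes C6, which was dim in young nerve, and C4b (0.86 ± 0.17) were also higher. The major urinary protein genes Mup1 (-3.09 ± 0.39) and Mup2 (-2.65 ± 0.36) had the largest falls; they belong to a family of near-identical genes whose probes cannot be assumed to tell them apart. Skeletal muscle markers were higher in old day 0 nerve (1 of 23 called, also adjusted over the list alone; median log2 difference 0.99, camera adjusted p = 0.00226, and adjusted p = 0.538 with an estimated correlation), and without old day 0 replicate 2 the direction turned (adjusted p = 0.794).

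In uninjured nerve 573 genes passed, 179 higher and 394 lower in old animals, 75 of them at least 2-fold, and the arrays of the ages did not overlap for 27.6% of genes against 10% by chance. The count was 228 without young day 0 replicate 2, 242, 372 and 343 without old day 0 replicate 1, 2 or 3, 951 with array weights, 217 with array brightness in the model and 172 without the 4 arrays richest in muscle RNA, against a median of 176 over all 81 ways to leave out 1 array from each of the same 4 groups. Of the 38 lists 21 were called, 3 also with an estimated correlation. The calls of Gpnmb, Apoe, Fads2, Ugt8a, Mag, Col1a2, Ms4a7, Rbp7, C4b, Mup1, Mup2 and C6 ended in at least 1 alternative.

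**Figure D3:**
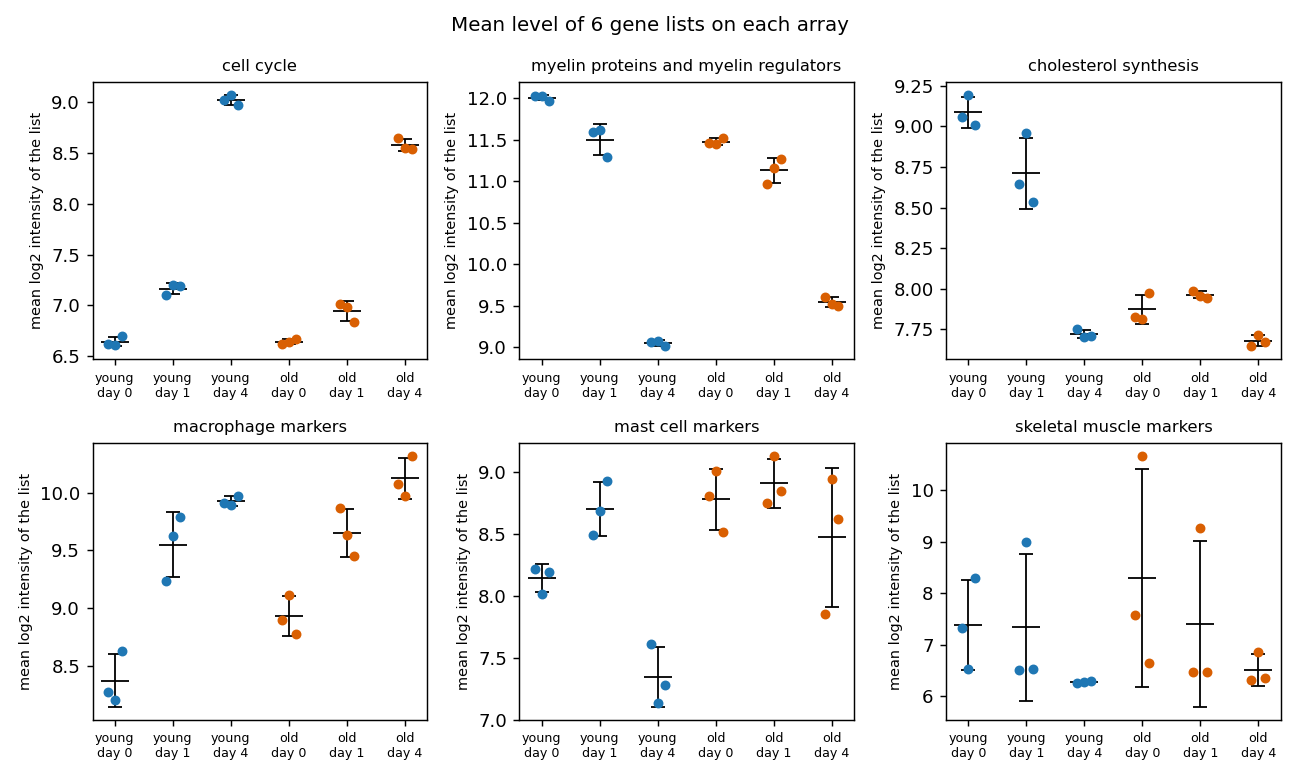
Mean log2 intensity of the measured members of 6 gene lists on each array (points, 3 arrays per group; bar, mean; whisker, SD). Cholesterol synthesis stood at 9.09 ± 0.10 in young and 7.87 ± 0.09 in old day 0 nerve, and skeletal muscle markers spread widely among the arrays of days 0 and 1.

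At day 1 after crush fewer genes passed between the ages than at day 0. Cholesterol synthesis genes were still lower in old nerve: 10 of 19 passed (16 adjusted over the list alone, median log2 difference -0.76, camera adjusted p = 5.1e-28). Examples were Cyp51 at -1.48 ± 0.16, Fdps at -1.29 ± 0.19 and Hmgcs1 at -1.10 ± 0.16. Of 28 genes for fibrillar collagens and matrix 7 were lower and 1 higher (10 and 2 adjusted over the list alone; median log2 difference -0.38, camera adjusted p = 2.5e-11). Examples were Col3a1 (-1.68 ± 0.25) and Mfap5 (-1.04 ± 0.12). Of 20 perineurial and nerve fibroblast markers 1 was lower (5 lower and 1 higher adjusted over the list alone; median log2 difference -0.18, camera adjusted p = 0.00844, and adjusted p = 0.0922 with an estimated correlation), and of 16 pericyte and smooth muscle markers 0 passed, also adjusted over the list alone (median log2 difference -0.35, camera adjusted p = 1.6e-04, and adjusted p = 0.212 with an estimated correlation). Of 32 cell cycle genes 4 were lower (8 adjusted over the list alone; median log2 difference -0.18, camera adjusted p = 2.9e-08). Examples were Prc1 at -0.76 ± 0.16 and Birc5 at -0.55 ± 0.11. Of 13 fatty acid synthesis genes 2 were lower (4 adjusted over the list alone; median log2 difference -0.23, camera adjusted p = 2.9e-08). Elovl6 differed by -1.46 ± 0.14.

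Of 21 myelin genes 5 were lower in old nerve (9 adjusted over the list alone; median log2 difference -0.19, camera adjusted p = 2.9e-08). Ugt8a differed by -1.31 ± 0.17. With running-number blocks the list's adjusted p was 0.366. The genes with the largest rise were Gpnmb (1.43 ± 0.21), the tight junction gene Cldn11 (1.26 ± 0.23), the netrin Ntn5 (1.10 ± 0.14), Shh (0.98 ± 0.21) and Vmn1r181 (0.95 ± 0.14), and those with the largest fall were Mup1 (-2.95 ± 0.39), Mup2 (-2.00 ± 0.36), Col3a1, Pon1 (-1.63 ± 0.36) and the fibroblast gene Pi16 (-1.51 ± 0.30). With running-number blocks the Shh difference was 0.53, not called. Jun (0.17 ± 0.17), Gdnf (0.24 ± 0.14), Ngfr (0.12 ± 0.16), Sox2 (0.11 ± 0.14), Olig1 and Egr2 (0.23 ± 0.17) did not pass.

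At day 1, 106 genes passed between the ages, 21 higher and 85 lower in old nerve, 40 of them at least 2-fold, the groups did not overlap for 14.05% of genes (10% by chance), and 6 of the 18 called lists held with an estimated correlation. The count was 57 without young day 1 replicate 1, 67 without young day 1 replicate 2, 59 without old day 1 replicate 1, 65 without old day 1 replicate 2, 17 without the 4 arrays richest in muscle RNA, 41 from the compared groups alone and 419 with array weights. The calls of Fdps, Hmgcs1, Col3a1, Prc1, Birc5, Gpnmb, Cldn11, Shh, Vmn1r181, Mup1, Mup2, Pon1 and Pi16 ended in at least 1 alternative.

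At day 4 old nerve held more myelin gene expression and less cell cycle gene expression than young nerve. Prx stood at 8.26 ± 0.20 in old and 6.93 ± 0.21 in young nerve (log2 difference 1.33 ± 0.14, limma adjusted p = 6.8e-05), and of 21 myelin genes 8 were higher and 0 lower (13 higher adjusted over the list alone; median log2 difference 0.57, camera adjusted p = 6.7e-16). Examples were Dhh, the hedgehog ligand of myelinating Schwann cells (1.07 ± 0.11), and Pmp22 (0.81 ± 0.13). Of 32 cell cycle genes 11 were lower (21 adjusted over the list alone; median log2 difference -0.42, camera adjusted p = 1.1e-27). Examples were Plk1 at -0.73 ± 0.13, Top2a at -0.72 ± 0.13 and Kif22 at -0.64 ± 0.09. Of 8 mast cell markers 5 were higher (6 adjusted over the list alone; median log2 difference 1.22, camera adjusted p = 3.6e-12). Examples were the proteases Cpa3 (1.63 ± 0.33) and Cma1 (1.37 ± 0.25) and the receptor chain Fcer1a (1.52 ± 0.33). The list was already higher in old nerve at day 0 (median 0.61, camera adjusted p = 0.00179, and adjusted p = 0.247 with an estimated correlation). In young nerve 6 of the 8 fell by day 4 (median -0.83, camera adjusted p = 0.0288, and adjusted p = 0.391 with an estimated correlation). The day 4 interaction of the list was not called (median 0.57, camera adjusted p = 0.0544). The mean of the list was 8.95 and 8.63 on old day 4 replicates 2 and 3 and 7.85 on replicate 1. With running-number blocks, which leave old day 4 replicate 1 alone in this comparison, the differences of Cpa3 (0.95), Cma1 (0.85) and Fcer1a (0.94) were not called.

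The largest rises in old nerve were those of Prl2c3 (2.33 ± 0.16) and Mrpplf3 (2.18 ± 0.15), related genes of the prolactin family that probes cannot be assumed to separate, followed by Cpa3, Saa3 (1.55 ± 0.31) and Fcer1a. The largest falls were those of the aldehyde dehydrogenase Aldh3a1 (-2.54 ± 0.15), Mup1 (-2.38 ± 0.39), the retinol-oxidizing enzyme gene Adh7 (-1.72 ± 0.19), Mup2 (-1.68 ± 0.36) and the growth factor binding protein Igfbp2 (-1.51 ± 0.17). Of 30 cytokines and chemokines 3 were higher (4 adjusted over the list alone; median log2 difference 0.33, camera adjusted p = 3.1e-05, and adjusted p = 0.281 with an estimated correlation; adjusted p = 0.0669 with running-number blocks). An example was Cxcl14 at 1.36 ± 0.21. Shh (0.53 ± 0.21, adjusted p = 0.411), Gdnf (-0.25 ± 0.14, its other probe of opposite sign here and in both interactions), Ngfr (-0.53 ± 0.16), Jun (-0.17 ± 0.17), Sox2 (-0.02 ± 0.14), Olig1 (-0.21 ± 0.13), Egr2 (0.57 ± 0.17) and Mbp (-0.13 ± 0.11) did not pass, and cholesterol synthesis was not called (median -0.02, 0 of 19 lower, 0 higher).

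At day 4, 165 genes passed between the ages, 56 higher and 109 lower in old nerve, 31 of them at least 2-fold, the groups did not overlap for 11.5% of genes (10% by chance), and 3 of the 13 called lists held with an estimated correlation. The count was 95 and 107 without young day 4 replicate 1 or 2, 103 and 94 without old day 4 replicate 2 or 3, 41 with running-number blocks, 90 without the 4 arrays richest in muscle RNA and 26 from the compared groups alone. The calls of Pmp22, Plk1, Top2a, Kif22, Cpa3, Cma1, Fcer1a, Saa3 and Mup2 ended in at least 1 alternative.

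The interaction asks whether the change after injury itself differs with age. By day 4, myelin genes had fallen less in old nerve: Pmp2, a lipid-binding myelin protein, by 2.65 ± 0.38 less and Prx by 1.93 ± 0.20 less. Of 21 myelin genes 11 passed with the smaller fall in old nerve (17 adjusted over the list alone; median log2 difference 0.99, camera adjusted p = 9.7e-24). Cholesterol synthesis genes differed the same way, 10 of 19 passing (16 adjusted over the list alone; median log2 difference 1.21, camera adjusted p = 7.5e-26). Examples were Sqle at 2.27 ± 0.28, Fdps at 2.17 ± 0.26 and Cyp51 at 2.18 ± 0.22. The genes of both lists started lower in old nerve (medians -0.49 and -1.22). Cholesterol synthesis was not called between the ages at day 4 (median -0.02), so its interaction reflects that lower start. Of 32 cell cycle genes 4 passed with the smaller rise in old nerve (15 adjusted over the list alone; median log2 difference -0.53, camera adjusted p = 4.8e-14). Cdc20 differed by -1.03 ± 0.22. Shh had the most negative interaction (-2.76 ± 0.30), followed by Aldh3a1 (-2.62 ± 0.21), Gpnmb (-1.75 ± 0.30, with 1 of its 3 other probes of opposite sign), Trem2 (-1.65 ± 0.32) and Btc (-1.54 ± 0.24). Of these, Shh, Gpnmb and Trem2 started higher in old nerve (log2 differences 3.28, 2.01 and 1.81 at day 0). They were not called between the ages at day 4, so their interactions reflect that higher start.

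No value is given here for the interactions of Mrpplf3, Prl2c3 and Kif11, which were at background in young day 0 nerve. Of 13 fatty acid synthesis genes 5 passed with a positive interaction (6 adjusted over the list alone; median log2 difference 0.39, camera adjusted p = 4.2e-07), Elovl6 at 1.42 ± 0.20. This list started lower in old nerve (median -0.45 at day 0). It was not called between the ages at day 4 (median -0.01, 0 of 13, camera adjusted p = 0.966), so its interaction reflects that lower start. Of 23 macrophage markers 2 passed with a smaller rise in old nerve, also adjusted over the list alone (median log2 difference -0.34, camera adjusted p = 0.00448, and adjusted p = 0.560 with an estimated correlation). The list started higher in old nerve (median 0.54 at day 0). It also stood higher there at day 4, with 0 of 23 called (median 0.19, camera adjusted p = 0.00644, and adjusted p = 0.480 with an estimated correlation). Gdnf (-0.63 ± 0.19), Ngfr (-0.92 ± 0.22, adjusted p = 0.0509), Egr2 (0.96 ± 0.24, adjusted p = 0.0640), Jun (0.16 ± 0.24), Sox2 (-0.10 ± 0.20) and Olig1 (-0.12 ± 0.19) did not pass. At day 4 the interaction of 168 genes passed (110 positive, 58 negative), and 4 of 11 called lists held with an estimated correlation. Leaving out 1 array gave between 102 (without old day 4 replicate 2 or 3) and 292 (without old day 4 replicate 1), with 107, 109 and 103 without young day 0 replicate 2, old day 0 replicate 1 or young day 4 replicate 2. Running-number blocks gave 56, cyclic loess 104 and leaving out the 4 arrays richest in muscle RNA 59. Over all 81 ways to leave out 1 array from each of the same 4 groups the median was 67, and 27 gave as few as the muscle-rich choice. The calls of Cdc20, Gpnmb, Trem2 and Elovl6 ended in at least 1 alternative.

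At day 1 the interaction passed for 2 genes, Shh (-2.30 ± 0.30, limma adjusted p = 0.00442), which rose less from its higher start in old nerve, and the histone gene H2ac24 (-1.49 ± 0.19, adjusted p = 0.00442), and 892 genes had an unadjusted p under 0.05. With array weights 35 genes passed. Of the 38 lists 16 were called and 0 held with an estimated correlation; the smallest adjusted p was that of cholesterol synthesis (median log2 difference 0.40, camera adjusted p = 1.8e-08, and adjusted p = 0.177 with an estimated correlation; 5 of 19 positive adjusted over the list alone). Gdnf (-0.14 ± 0.19), Jun (0.49 ± 0.24), Ngfr (-0.28 ± 0.22), Sox2 (0.03 ± 0.20) and Egr2 (0.63 ± 0.24) did not pass, and no value is given for Olig1, at background in young day 1 nerve. Shh was not called with the mean of its probes (-1.32), with the authors' processed values (-1.85) or without the 4 arrays richest in muscle RNA (-2.21). H2ac24 was not called with running-number blocks (-1.37) or without those 4 arrays (-1.52), with differences near the main value. Without those 4 arrays 0 genes passed, and 47 of 81 equal choices of arrays gave as few (median 0, range 0 to 11).

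Between day 1 and day 4, cell cycle genes rose at both ages (young 28 of 32, median log2 fold change 1.72, camera adjusted p = 1.6e-35; old 28 of 32, median log2 fold change 1.38, camera adjusted p = 9.7e-34), and myelin genes fell (young 18 of 21, median log2 fold change -2.48, camera adjusted p = 2.4e-27; old 15 with 1 higher, median log2 fold change -1.85, camera adjusted p = 3.3e-18). Of 20 immediate early genes 12 went down and 2 up in young nerve (median log2 fold change -0.54, camera adjusted p = 4.0e-05), and 12 down and 2 up in old nerve (median log2 fold change -0.47, camera adjusted p = 5.5e-06). Neutrophil markers fell as well, 10 of 19 in young nerve (median log2 fold change -1.002, camera adjusted p = 2.0e-05, and adjusted p = 0.222 with an estimated correlation) and 10 in old nerve (median log2 fold change -1.26, camera adjusted p = 8.5e-06, and adjusted p = 0.245 with an estimated correlation). So did erythroid and blood markers, 4 of 12 in young nerve (median log2 fold change -0.25, camera adjusted p = 0.0139, and adjusted p = 0.327 with an estimated correlation) and 5 in old nerve (median log2 fold change -1.15, camera adjusted p = 1.7e-04, and adjusted p = 0.230 with an estimated correlation). Old day 1 replicate 3 stood above the other 2 arrays of its group (list mean 9.36 against 8.42 and 8.57). Myelin genes differed between the ages in this step (9 of 21 with the smaller fall in old nerve, median log2 difference 0.71, camera adjusted p = 1.7e-23). Between these days 2711 genes passed in young nerve (1532 higher), 2420 in old nerve (1381 higher) and 43 in the interaction. The last count was 26 without old day 4 replicate 2, 73 without old day 4 replicate 1, 92 with array weights and 3 with running-number blocks. Without the 4 arrays richest in muscle RNA it was 3, which 3 of 81 equal choices of arrays reached (median 18, range 3 to 55).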

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

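The brightness tests of the cholesterol, myelin and cell cycle genes, the tests with running-number blocks, the share of the day 1 rise and the splits of the samples were written down after their results had been seen, and the other tests before, with settings and patterns all chosen after seeing the data.

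Cholesterol synthesis genes stood out by their interaction of age and injury (median 1.21 at day 4 and 0.40 at day 1). The day 1 call was lost with an estimated correlation (camera adjusted p = 0.177). The genes were lower in old nerve before injury (median -1.22) and were not called between the ages at day 4 (median -0.02, 0 of 19). Their day 4 interaction thus reflects the lower start in old nerve. With array brightness in the model the day 0 median was -1.32, and without the 4 arrays richest in muscle RNA it was -1.06, both with the list still called, which argues against brightness and muscle RNA as the whole cause. A smaller share of all Schwann cells would lower their other markers as much, but 9 Schwann cell markers outside the myelin and repair lists had a median of 0.0253 (SD 0.21). These markers leave out the myelin list, itself lower in old day 0 nerve (median -0.49). A smaller share of myelinating Schwann cells was therefore not tested and stays open. A lower rate of sterol synthesis in Schwann cells of aged nerve may be the biological explanation. It is a hypothesis that these data raised and cannot test apart from age. The level in old day 0 nerve already lay near that of injured nerve at day 4.

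Myelin genes fell less and cell cycle genes rose less by day 4 in old nerve (median interactions 0.99 and -0.53). With array brightness in the model these medians were 1.16 and -0.39, both still called. No slide and no order of hybridisation is named for the arrays. The deposited columns of non-normalized values step through the running-number blocks in turn, position by position. Slides made up of these blocks could give that order, so the blocks may be slides, which was not tested. The running number cannot be told apart from age here. With running-number blocks the medians were 1.09 and -0.37, but old day 4 replicates 2 and 3 are alone in their block. These values therefore rest on old day 4 replicate 1. Uninjured nerve in the old day 4 samples would hold back other falling genes too, on the log2 scale more the deeper their fall. Against that, 99 other genes with an average fall over 2 log2 units (median -2.37, myelin list -2.06) had a median interaction of 0.21 (SD 0.63). This lies below the interaction of the myelin genes by more than the spread. It cannot settle the day 4 part, because the myelin interaction also holds their lower start at day 0. No day 4 difference between the ages is given for those 99 genes to set beside that of the myelin genes (0.57). For cell cycle genes, 98 other genes that rose over 2 log2 units also rose less in old nerve (median -0.45, SD 0.67), as uninjured nerve would have it. A share of uninjured nerve large enough for this would also cap every fall in old nerve. There the myelin list (16 of 21 fell, 2 rose) had a median log2 fold change of -2.09 by day 4, with a largest fall of -5.28. This argues against uninjured nerve as the whole cause of the smaller cell cycle rise. Myelin genes were already lower in old nerve at day 0 (median -0.49) and higher at day 4 (0.57), so that the lower start enters their interaction. A slower breakdown of the myelin program with age was not tested. For the day 4 part of the myelin pattern it stays open beside the running number and uninjured nerve in the samples. For the cell cycle part a generally smaller rise, biological or from another difference in the tissue taken, stays open.

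Shh rose less from day 0 in old nerve (-2.30 at day 1 and -2.76 at day 4), and its day 0 level was 3.28 log2 units higher there. The difference at day 0 was 3.50 with array brightness in the model and 3.12 without the 4 arrays richest in muscle RNA, both called. Nerve at day 1 of injury mixed into the old day 0 samples would bring all abundant early injury genes. Old day 0 nerve showed a median of 1.04% of the young day 1 rise over 19 other genes that rose more than 3 log2 units. Their upper quartile was 2.28% and the highest 14.02%, against 24.4% for Shh. These 19 genes were chosen by their rise at day 1, so nerve at a later stage of injury in these samples was not tested. Other genes that rise after injury, among them Trem2 and Gpnmb, were also higher in old day 0 nerve. A higher expression of Shh in aged nerve without these 19 early genes is a candidate explanation, found and tested on the same data.

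The day 1 response also differed between ages for the lists myelin proteins and myelin regulators (0.0637), cell cycle (-0.19), macrophage markers (-0.38), alternatively activated macrophage (-0.30), neutrophil markers (0.50), T and NK cell markers (-0.12), mast cell markers (-0.42), MHC class I presentation (-0.13), complement (-0.28), interferon response (-0.16), cytosolic ribosomal proteins (-0.15), endothelial markers (-0.28), pericyte and smooth muscle markers (-0.40), adipocyte markers (-0.67) and skeletal muscle markers (-0.93) by median interaction, and none of these held with an estimated correlation. The direction turned for neutrophil markers with running-number blocks (adjusted p = 0.235), and for skeletal muscle markers without the 5 arrays richest in muscle RNA (0.113) and without old day 0 replicate 2 (0.552). At day 4 it differed for the lists repair Schwann cell (-0.16), fatty acid synthesis (0.39), macrophage markers (-0.34), T and NK cell markers (-0.17), interferon response (-0.27), fibrillar collagens and matrix (0.30), cytosolic ribosomal proteins (-0.13) and antioxidant and heat shock response (-0.14), of which fatty acid synthesis held. Fatty acid synthesis, like cholesterol synthesis, started lower in old nerve (median -0.45 at day 0) and was not called between the ages at day 4 (median -0.01). H2ac24 differed at day 1 (-1.49). The named genes whose day 4 response differed were Pmp2 (2.65), Mrpplf3 (2.30), Sqle (2.27), Prl2c3 (2.21), Cyp51 (2.18), Aldh3a1 (-2.62), Gpnmb (-1.75), Trem2 (-1.65) and Btc (-1.54), then Ncam1 (1.39), Dhh (1.62), Prx (1.93), Cldn19 (1.33), Fdps (2.17), Nsdhl (1.54), Elovl6 (1.42), Acsl3 (1.12) and Slc25a1 (0.90), then Elovl1 (1.03), Kif11 (-0.60), Cdc20 (-1.03), Top2a (-0.80), Kif22 (-0.54), Lgals3 (-0.83), Lox (1.23) and Mfap5 (0.72). Of these, Mrpplf3, Prl2c3 and Kif11 were at background in young day 0 nerve, so their values are not exact.

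For the comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05; in each, 1 of 10 splits, the real one, gave as many genes, with 3266 genes and a highest other of 3 (young day 1), 4688 and 0 (young day 4), 2883 and 0 (old day 1), 4426 and 0 (old day 4), 573 and 0 (ages at day 0), 106 and 88 (ages at day 1), 165 and 25 (ages at day 4), 2711 and 1 (young day 4 against day 1) and 2420 and 0 (old day 4 against day 1). For the interaction at day 1, 13 of 100 splits gave at least the 2 genes seen, so chance is not excluded; the highest other split gave 308, many times the real count, which points to a structure of the samples. That split keeps the labels of day 0 and exchanges most of those of day 1, so it comes near the sum of the age differences; the full exchange, which was not drawn, gave 693. For the interaction at day 4, 3 of 100 splits gave at least 168 genes, a share under 0.05, and the highest other split (453) exchanges the age labels at day 4 alone, so that it tests the sum of the age differences; the next gave 264. For the step from day 1 to day 4, 2 of 100 splits gave at least 43 genes, and the highest other gave 163, several times the real count, which points to a structure of the samples whose cause was not tested. That split exchanges 1 array of each age at day 4, and the sum of the age differences, not drawn, gave 230.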

How the results depend on the processing

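Brightness, running-number blocks, the settings without muscle-rich arrays and leave-one-out for lists were chosen after seeing the data. Counts of genes outside 1.5 times the value in the report were, with a floor of 2-fold, 423 (young day 1), 1254 (young day 4), 488 (old day 1), 1120 (old day 4), 75 (ages, day 0), 40 (ages, day 1), 31 (ages, day 4), 76 (interaction, day 4), 657 (young day 1 to 4), 536 (old day 1 to 4), 27 (interaction, day 1 to 4); without the 5 arrays richest in muscle RNA, 1430 (young day 1), 529 (old day 1), 2215 (old day 4), 26 (ages, day 0), 26 (ages, day 1), 77 (ages, day 4), 0 (interaction, day 1), 16 (interaction, day 4), 1801 (young day 1 to 4), 1520 (old day 1 to 4), 4 (interaction, day 1 to 4); without the 4 richest, 1731 (young day 1), 1589 (old day 1), 172 (ages, day 0), 17 (ages, day 1), 90 (ages, day 4), 0 (interaction, day 1), 59 (interaction, day 4), 3 (interaction, day 1 to 4); with running-number blocks, 2212 (young day 4), 442 (old day 1), 1517 (old day 4), 41 (ages, day 4), 1 (interaction, day 1), 56 (interaction, day 4), 1267 (old day 1 to 4), 3 (interaction, day 1 to 4); with array weights, 951 (ages, day 0), 419 (ages, day 1), 35 (interaction, day 1), 92 (interaction, day 1 to 4); from the compared groups only, 41 (ages, day 1), 26 (ages, day 4); with brightness, 217 (ages, day 0); with the mean of probes, 1 (interaction, day 1); with cyclic loess, 104 (interaction, day 4). The correlation of ages at day 1 was 0.763 with running-number blocks. A fold floor lowers a count by construction; the other causes were not tested. No count moved beyond 1.5 times without background correction, with the authors' values, with either other filter, with an intensity trend, or with the replicate number as a block, for which 0 of 15 group pairs had all same-numbered correlations over 0.1.

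Leaving out 1 array gave, as lowest and highest, 2373 and 3212 (young day 1), 4160 and 4298 (young day 4), 1996 and 2753 (old day 1), 3641 and 4210 (old day 4), 228 and 461 (ages, day 0), 57 and 119 (ages, day 1), 94 and 179 (ages, day 4), 2 and 3 (interaction, day 1), 102 and 292 (interaction, day 4), 2207 and 2639 (young day 1 to 4), 1781 and 2558 (old day 1 to 4), 26 and 73 (interaction, day 1 to 4); the correlations ran from 0.778 to 0.868 at day 1 and from 0.854 to 0.899 at day 4. For muscle-rich arrays, leaving out 1 array from each of the same 4 groups in all 81 ways gave a median of 176 genes between ages at day 0 (range 82 to 379, 40 as low as the muscle-rich choice), 36 at day 1 (16 to 149, 2 as low), 115 at day 4 (77 to 145, 5 as low) and 18 in the interaction from day 1 to 4 (3 to 55, 3 as low).

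Directions turned, with no cause tested, for H2-Aa at old day 4 with running-number blocks (-0.0520) and, by adjusted p of the turned list, with the same blocks for cytokines and chemokines at young day 4 (0.875) and old day 4 (0.718), basement membrane at old day 4 (0.861), neutrophil markers between ages at day 1 (0.382) and in its interaction (0.235), endothelial (0.654) and adipocyte markers (0.619) at day 1. Skeletal muscle markers turned between ages at day 0 (0.0260) and in the day 1 interaction (0.113) without the 5 muscle-rich arrays, and without old day 0 replicate 2 (0.794 and 0.552, against 4.7e-08 and 9.9e-08 without replicate 3), and endothelial markers between ages at day 1 without young day 1 replicate 1 (0.745, against 2.8e-04 without replicate 3). Of 472 named results 152 lost their call with running-number blocks (most comparisons then rest on 1 array of a group), 149 without the 5 and 84 without the 4 muscle-rich arrays, 46 from the compared groups only and 22 with brightness. The planned correction by control probes or detection p-values and the slide term were not run. Signal over background limits what dim genes can show, with 53.5% to 62.5% of probes above it.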

Other observations

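The lists described here were fixed before the data were examined, and the counts over all 3 days and the genes named from them were chosen after their values were seen. Genes of the circadian clock were lower at day 4 after injury. In young nerve 9 of 15 fell and 1 rose (11 and 1 adjusted over the list alone, median log2 fold change -0.72, camera adjusted p = 0.00556, and adjusted p = 0.0720 with an estimated correlation). In old nerve 8 fell and 1 rose, also adjusted over the list alone (median log2 fold change -0.57, camera adjusted p = 0.0122, and adjusted p = 0.122 with an estimated correlation). Among the genes that fell were the repressor Nr1d1 (-1.54 ± 0.24 in young and -1.67 ± 0.24 in old nerve) and Per1 (-1.38 ± 0.23 and -1.43 ± 0.23). Neither was called at either age with running-number blocks, which rest on single arrays here. The labels do not give the hour at which nerves were taken. Blood vessel genes were lower too, with 12 of 21 endothelial markers down at day 4 in young nerve (median log2 fold change -0.60, camera adjusted p = 1.3e-04, and adjusted p = 0.333 with an estimated correlation) and 13 in old nerve (median log2 fold change -0.54, camera adjusted p = 9.6e-04, and adjusted p = 0.363 with an estimated correlation). An example was the junction gene Cldn5 (-1.498 and -1.18), which was not called with running-number blocks at either age. With these blocks the list was called at neither age (adjusted p = 0.0824 and 0.147). Of 11 genes of MHC class II presentation 6 rose at day 4 in old nerve (median log2 fold change 0.56, camera adjusted p = 0.0122, and adjusted p = 0.363 with an estimated correlation; 0.542 with running-number blocks). H2-Ab1 changed by 1.08, not called with these blocks. In young nerve 7 rose and 2 fell, and the list was not called (median 0.49, adjusted p = 0.121).

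The 3 age comparisons share no array, and 15 genes passed in all of them: 2 were higher in old nerve on all 3 days, 11 were lower and 2 changed direction. Each gene has one variance estimate for all 3 comparisons, so its calls are not independent. Lower in old nerve at day 0, 1 and 4 were the collagen VI genes Col6a1 (-1.20, -1.01 and -0.52) and Col6a2 (-1.29, -1.01 and -0.99), the collagen Col26a1 (-1.69, -1.29 and -0.69), the membrane protein gene Itm2a (-1.32, -1.44 and -1.06), the guidance cue Sema5a (-0.90, -0.55 and -0.64), the kinase Prkcq (-1.01, -0.53 and -0.58), Cd276 (-0.61, -0.48 and -0.76), Anln (-0.62, -0.61 and -0.69), Pank1 (-0.48, -0.42 and -0.43), and the urinary protein genes Mup1 (-3.09, -2.95 and -2.38) and Mup2 (-2.65, -2.00 and -1.68), as log2 differences. Higher on all 3 days were the tight junction gene Cldn11 (0.96, 1.26 and 1.15) and the steroid reductase gene Srd5a2 (0.66, 0.45 and 0.39). The myelin genes Cldn19 (-0.67, -0.63 and 0.66) and Pmp2 (-1.48, -1.48 and 1.16) were lower in old nerve on days 0 and 1 and higher on day 4. Each of the 15 genes lost its call on at least 1 of the 3 days in at least 1 of 20 alternative settings, most often Cd276 in 15 of them on day 1, and Pmp2 in 14, Srd5a2 in 14, Col6a1 in 13 and Pank1 in 11 on day 4, so the set depends on the settings.

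Erythroid genes stood high on old day 1 replicate 3 and old day 0 replicate 1. Alas2, the heme synthesis enzyme of red cells, reached 10.63 and 9.82 there (median of 18 arrays 7.49), and Slc4a1 reached 9.77 and 9.54 (median 6.46). The muscle actin Acta1 reached 13.45 on old day 0 replicate 2 (median 6.75). The Y-linked genes Ddx3y and Eif2s3y were above background on all 18 arrays, with a lowest level of 9.23 and 7.33, and Xist was above background on 3 arrays, with a highest level of 6.40. Lists with no call in any of the 12 comparisons included the sex-linked genes, and oxidative phosphorylation was called in old against young at day 0 alone (median 0.10, camera adjusted p = 0.0307, and adjusted p = 0.358 with an estimated correlation).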
